A study of Homo sapiens with 5 samples.

How the data were processed

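RNA-seq was measured in 5 libraries from 2 human hepatocellular carcinoma cell lines. SNU-387 cells carried an empty vector, a SALL4A vector or a SALL4B vector, and SNU-398 cells were either untreated or carried a SALL4 knockdown. Each of the 5 groups held 1 library. Per the labels' protocols, cells were grown in RPMI medium with 10% serum, total RNA was purified on RNeasy columns, and libraries were made with a ScriptSeq Complete Gold kit, which removes ribosomal RNA and keeps RNA without a poly(A) tail. The protocol field lists lentiviral transduction and puromycin selection for every sample, while the source label of the control SNU-398 sample calls the cells untreated. The cell line field of both samples titled SNU-398 reads SNU-387. Groups followed the titles, and correlations between libraries were used as a check of that choice.

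The deposited values were FPKM per gene, made by the authors. The submitters' processing notes name TopHat2, SAMtools, Cufflinks and Cuffdiff without versions, and the builds GRCh38 and hg38. The gene annotation, the fragment length and whether the libraries were normalised together are not given in the sources used here. No deposited column held read counts, so no count test was run.

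Each table had 26032 rows. The 17 rows whose gene name was a dash were left out, and rows sharing a symbol were summed, which affected 450 symbols and left 24544 symbols. Of these, 333 combined the names of several genes at one locus, whose values cannot be divided between them. Mitochondrially encoded OXPHOS mRNAs were not analysed here because none of the symbols of that list had a row. Strand use in counting is not given in the sources used here, so overlapping antisense genes could not be told apart from their partners, and paralogs and pseudogenes could share reads.

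Depth was estimated from the steps between low FPKM values, using 1-transcript genes of GENCODE 29 for length. The estimates were 11.8 M (mega) fragments for empty vector, 23.2 M for SALL4A, 8.73 M for SALL4B, 21.1 M for untreated and 7.09 M for knockdown. At 1 FPKM, a gene with a 2 kb transcript then had about 23.6, 46.4, 17.5, 42.2 and 14.2 fragments in the same order. Values near 1 FPKM in the SALL4B and knockdown libraries were therefore the least precise.

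Ratios were computed as log2 of (FPKM + 1) over (FPKM + 1) for genes at 1 FPKM or more in either library of a pair. This scale understates the change of genes with low values. Genes were counted where the ratio reached 2-fold. With 1 library per group there is no replicate check on any difference, and no p-value was computed. Reference coordinates are GRCh38, from GENCODE 29.

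Before the data were examined, 37 gene lists were fixed, covering the OXPHOS complexes I to V and other mitochondrial functions, metabolism, stress and cytokine responses, proliferation, chromatin partners of SALL4 and markers of cell types. The union of the 5 complex lists is called nuclear OXPHOS. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, with sampling from the genes outside the list. A list was said to stand apart below the percentile 2.5 or above 97.5. This describes the pair of libraries and says nothing about variation between cultures. Lists with fewer than 3 members at 1 FPKM were not scored. The overlap of both isoforms was compared with 100 simulations of 2 unchanged libraries over 1 shared control, with noise resampled from the ratios of SALL4A to SALL4B, which treats isoform differences as noise. Counting overlaps in that simulation was added after the data were seen.

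Named genes also followed a rule fixed at that time. It took the 10 highest and 10 lowest ratios per main pair and the 5 highest and 5 lowest for SALL4A against SALL4B, among genes at 5 FPKM or more in the higher library. Small and structural RNAs recognised by a symbol prefix, clone names, XIST and Y-linked genes were left out, and the prefixes did not cover the small RNA SNAR-G1. Genes that moved in opposite directions with overexpression and knockdown were limited to 8 per direction, and each list to the 2 members with the largest changes and the 2 with the highest expression.

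The functions were tested on simulated data built from the empty vector library, with 12115 genes and a log2 spread of 0.25 between libraries. All 50 genes raised 3-fold and all 50 raised 6-fold were counted, as were 38 of 49 genes lowered 3-fold, and 0 of 50 genes raised 1.5-fold. None of 11844 unchanged genes was counted, which that small spread made near certain. The ratios of the real pairs had standard deviations of 0.669 to 1.052 across genes, real changes included. The simulation therefore gives no rate of false counts for the real pairs. Of 400 unchanged lists, 27 (6.8%) fell outside the percentile limits. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

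Alternatives fixed in advance were other pseudocounts (0.1 and 5 FPKM), a common total, centring on the median ratio, a common upper quartile, the highest row of a symbol, other filters, a 1.5-fold rule, unmatched random lists, means over members, the OXPHOS list without each complex, and tissue-restricted subunit isoforms added to it. Alternatives added after seeing the data were a correction for expression, transcript length and GC content, and a common total without small RNAs. Others left out small RNAs and transcripts under 1 kb, or subtracted an estimated share of SNU-387 RNA from the knockdown library. Small RNAs here included host genes with symbols starting SNHG or GAS5, while other snoRNA hosts were not matched by name. Subtracting the share left the SNU-387 pairs unchanged. Centring shifts all ratios of a pair alike, so it could not end the call of a list. Counts of alternatives that ended a call are therefore given out of a total that includes some unable to do so.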

Results

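The study measured transcript levels in liver cancer cells with raised or lowered SALL4, a zinc finger transcription factor of embryonic and fetal tissue that is re-expressed in some tumours. SNU-387 and SNU-398 are established human hepatocellular carcinoma lines. The series title names oxidative phosphorylation (OXPHOS) vulnerabilities linked to SALL4, so nuclear OXPHOS genes were the first gene list examined. There were 3 SNU-387 libraries (empty vector, SALL4A, SALL4B) and 2 SNU-398 libraries (untreated, knockdown), 1 per group, and no value below has replicate error. Estimated depth ranged from 7.09 M fragments in the knockdown library to 23.2 M in the SALL4A library. Across 24544 symbols, correlations of log2(FPKM + 1) were 0.932 to 0.977 between libraries of the same titled line and 0.829 to 0.857 between lines, although the cell line field names SNU-387 for all 5 samples. The share of summed FPKM listed under small nucleolar RNAs (snoRNAs) was 7.14% in empty vector, 13.2% in SALL4A, 8.1% in SALL4B, 1.04% in untreated and 37.1% in knockdown cells.

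SALL4 transcript followed the labels in every library. SALL4 (chromosome 20, 51782331 to 51802520, GRCh38) was at 0.117 FPKM with empty vector, 23.1 FPKM with SALL4A and 10.4 FPKM with SALL4B, log2 ratios of 4.43 and 3.35. In SNU-398 it was at 39.4 FPKM in untreated cells and 7.45 FPKM after knockdown, a log2 ratio of -2.26 and 18.9% of the untreated level. The listed FPKM of both overexpressing libraries lay below that of untreated SNU-398 cells. Summed FPKM differed (451775 and 484167 against 330655) and joint normalisation is not known, so SALL4 amounts cannot be ranked across the lines. Of its paralogs, SALL2 was at 13.1 FPKM in untreated SNU-398 and 4.73 FPKM after knockdown, a log2 ratio of -1.29, and SALL1 was at -0.27. The SALL family list (3 genes, percentile 0.58) includes SALL4, so its position partly restates the knockdown, and its median is the value of SALL2. FPKM per gene does not separate the SALL4 isoforms.

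**Figure D1:**
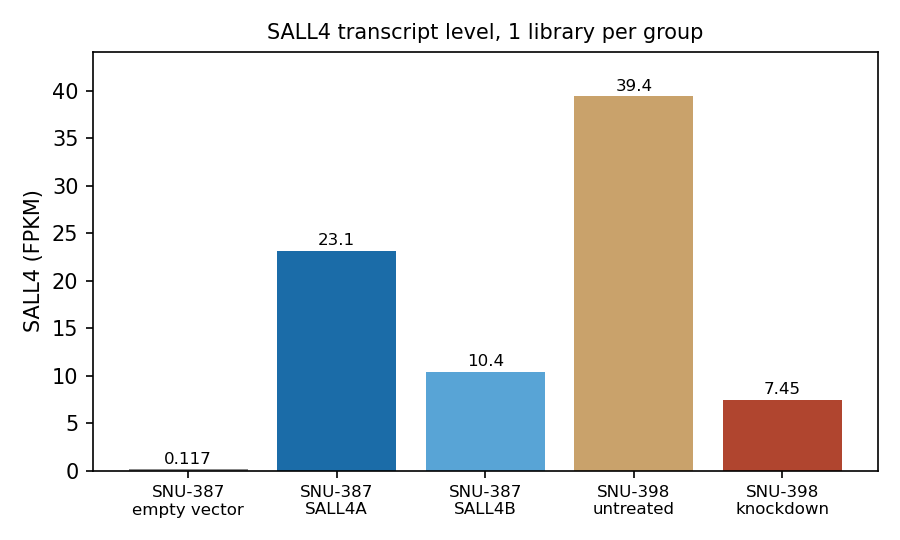
SALL4 level (vertical axis, FPKM from 0) in the 5 libraries, 1 bar per library and 1 library per group. The bars read 0.117, 23.1 and 10.4 FPKM in SNU-387 cells and 39.4 and 7.45 FPKM in SNU-398 cells.

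The first comparison asked what SALL4A changed in SNU-387 cells, which express almost no SALL4. Among the 10 most reduced genes, POSTN (periostin, chromosome 13, 37562583 to 37598844) was at 173 FPKM with empty vector and 6.38 FPKM with SALL4A (log2 ratio -4.56), and SULF2, which edits heparan sulfate, had a ratio of -3.61 and THBS2 of -3.49. SCG2, a granin, went from 236 to 14.9 FPKM (-3.90) and the keratin KRT7 from 47.6 to 2.13 FPKM (-3.96). Highest after SALL4A were the muscle and stress protein gene ANKRD1 (chromosome 10, 90912096 to 90921276, 0.935 to 43.4 FPKM, 4.52), SALL4 itself, the Notch ligand DNER (0.523 to 13.6 FPKM, 3.26) and the adhesion molecule NCAM1 (2.55 to 30.9 FPKM, 3.17).

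Other genes at the top of the SALL4A ranking were SAA1, an acute-phase protein (2.93), SPANXN3 (2.86), ECSCR (2.64), FLG, which encodes filaggrin (2.64), CEMIP (2.60) and EPPK1 (2.29). The lowest also held PAEP (-3.81), BEX1 (-3.69), the complement factor CFB (-3.64), the protease inhibitor SERPINA3 (-3.42) and TCN1 (-3.36). In all, 282 of 12441 genes lay at least 2-fold higher and 403 at least 2-fold lower. Higher genes made up 41.2% of these, against 25.6% with a common upper quartile, which shifted the median gene by -0.18, and 50.7% with a common total without small RNAs. Without small RNAs and transcripts under 1 kb, 164 genes remained on the higher side.

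Nuclear OXPHOS genes were lower with SALL4A. The 75 genes had a median log2 ratio of -0.22, at the percentile 0.05 of matched random lists, although no member reached 2-fold in either direction. The complex I subunits NDUFB10 (153 to 88.6 FPKM, -0.78) and NDUFB8 (-0.58) had the largest changes of their list, whose median was -0.25 (percentile 0.31). Medians were -0.08 for complex II, -0.27 for complex III, -0.33 for complex IV and -0.17 for complex V, all within their random ranges. COX7C was at -0.51 and COX5A at 0.55. Without complex I the median of the other complexes was -0.17 (percentile 5.29), and correction for transcript length and GC content brought the whole list to -0.11 (percentile 0.61).

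Other mitochondrial lists moved less uniformly with SALL4A. Mitochondrial ribosomal proteins had a median of -0.11 (percentile 2.06), with MRPL12 at 0.995 and MRPL15 at 0.90 against that direction, and 4 of 14 alternatives ended that call. Fatty acid oxidation genes stood below the random range (-0.30), with CPT1A, the carnitine acyltransferase that admits fatty acids to mitochondria, at -0.78. Mitochondrial protein import stood above it (0.16), with TOMM40 at 0.76. A common upper quartile, which shifts all genes, moved that median to -0.037 and its percentile only to 97.97, while 2 of 14 alternatives ended the call. OXPHOS assembly factors (-0.01), TCA cycle genes (0.01) and genes of mitochondrial DNA upkeep (0.13) were within range.

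Several stress, cytokine and metabolic lists stood below their ranges with SALL4A. Interferon response genes had a median of -0.89 (percentile 0.00) with 9 of 26 at least 2-fold lower, among them IFITM1 (11.8 to 1.504 FPKM, -2.36) and OAS1 (-1.85). Hypoxia response genes were at -0.60 (percentile 0.00), with the carbonic anhydrase CA9 at -1.90 and VEGFA at -1.15. Glycolysis genes were at -0.32, ALDOC at -1.37 and GAPDH at -0.44. NF-kB targets and inflammatory cytokines were at -0.27, with CCL2 at -2.60 and IL1B at -2.47, and the unfolded protein and integrated stress response was at -0.27, with HSP90B1 at -0.72. Cytosolic ribosomal proteins were at -0.24 (percentile 1.20), with RPL32 at -0.73. The calls of these ribosomal proteins and of the stress response were each ended by 2 of 14 alternatives.

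Cell type markers also differed with SALL4A. Fibroblast and stellate cell markers had a median of -1.12 (percentile 0.00) with 6 of 11 at least 2-fold lower, including DCN (30.4 to 2.73 FPKM, -3.07) and FAP (-2.98), while ACTA2 (1.54) and DES (1.20) were at least 2-fold higher. Mesenchymal transition markers were at -0.41, with FN1 at -1.89 while TAGLN was at 1.81. Endothelial markers stood above the range (1.77, 5 genes), with CDH5 at 5.06 FPKM against 0.333 and KDR at 3.46 FPKM against 0.238. CDH5 and KDR passed the filter only through the SALL4A library, and without a filter on low values the endothelial median was 0.086, within its range. Proliferation genes were at 0.35 (percentile 100), with UHRF1 (0.91) and MCM6 (0.89) highest, and replication-dependent histones were at 0.36. Of 34 lists, 4 stood above and 11 below their ranges, where 1.7 would be expected if genes varied independently. Members of a list can vary together and some lists share genes, so this difference does not measure an effect of SALL4A.

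The second comparison asked the same of SALL4B, the shorter isoform. Among the most reduced genes, the receptor gene IL13RA2 went from 104 to 0.257 FPKM (-6.38), POSTN from 173 to 1.61 FPKM (-6.06), COL6A3 from 313 to 7.07 FPKM (-5.28) and COL1A2 from 326 to 8.50 FPKM (-5.11). The laminin LAMA4 (-5.01), THBS2 (-4.94), the chemokine CCL2 (-4.94), TNFRSF11B (-4.85) and L1CAM (-4.80) followed. The highest were NTM (0.376 to 27.3 FPKM, 4.36), SAA1 (3.63), FLG (9.14 to 123 FPKM, 3.61), ITLN1 (3.61), the apolipoprotein APOA1 (3.603), SPANXN3 (3.51), ANKRD1 (3.47), CST7 (3.31) and EEF1A2 (3.15).

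With SALL4B, 390 of 12459 genes lay at least 2-fold higher and 605 lower. Higher genes made up 39.2% of these, against 16.4% with a common upper quartile, which shifted the median gene by -0.31. Nuclear OXPHOS genes had a median of 0.14, within the random range (percentile 79.19). NDUFA3 was at 1.18, USMG5 at 1.08, COX6C at 0.83 and UQCR10 at 0.58. The complexes had medians of 0.08, 0.16, 0.26, 0.22 and 0.26 from I to V, none of them apart.

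Mitochondrial ribosomal proteins (0.24, percentile 99.96) and OXPHOS assembly factors (0.25, percentile 99.80) stood above their ranges with SALL4B. MRPS34 went from 63.4 to 126 FPKM (0.98), and NDUFAF2 from 120 to 232 FPKM (0.94). With a common upper quartile both medians took the other sign, -0.095 and -0.074, and kept percentiles of 99.99 and 99.84. Protein import (0.21), mitochondrial DNA upkeep (0.16), TCA cycle genes (0.08), fatty acid oxidation (0.05) and NRF2 targets (0.24) were within range, the last with OSGIN1 at 1.80.

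Interferon response genes were reduced with SALL4B too, with a median of -0.63 (percentile 0.00) and 7 of 26 at least 2-fold lower. IFITM1 was at -3.44 and IFI27 at -2.34. Hypoxia genes (-0.26, CA9 at -2.37), glycolysis genes (-0.19, the glucose transporter SLC2A3 at -1.15) and cholesterol synthesis genes (-0.24, STARD4 at -0.77) stood below. Mesenchymal transition markers were at -0.48, with FN1 at -1.97 and VIM at 1.82. Fibroblast markers were at -0.23 (percentile 2.38), with FAP at -3.98 and LUM at 0.89, and 4 of 14 alternatives ended that call. Leukocyte markers (5 genes, -0.73) also stood below.

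Immediate early genes stood above the range with SALL4B (0.59, percentile 100), with EGR1 going from 2.76 to 15.6 FPKM (2.15). Biliary and progenitor markers were at 0.72 (7 genes, percentile 99.96), with PROM1 at 2.32 and CD24 at 1.03 while KRT7 was at -4.75. Without a filter on low values that median was -0.028. Of 33 lists, 4 stood above and 7 below. Lists within range for SALL4B were proliferation (0.08), histones (0.17), cytosolic ribosomal proteins (0.17), NF-kB targets (-0.03), stress response genes (0.04) and p53 targets (-0.11).

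**Figure D2:**
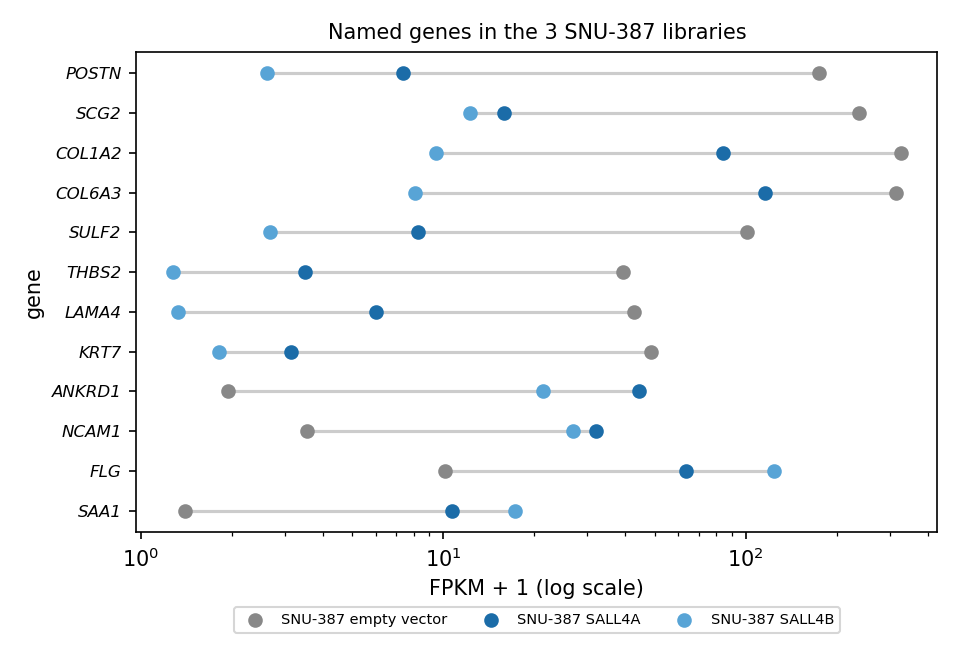
FPKM + 1 on a logarithmic horizontal axis for 12 named genes (rows) in the 3 SNU-387 libraries, 1 point per library, with grey lines joining the lowest and highest. POSTN sits at 173 FPKM with empty vector and at 6.38 and 1.61 FPKM with SALL4A and SALL4B, while ANKRD1 sits at 0.935, 43.4 and 20.4 FPKM.

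Some changed genes were shared between the isoforms, and both ratios use the same empty vector library. At least 2-fold lower in both were 234 genes, and 95 were at least 2-fold higher in both. These counts cover 12217 genes that passed the 1 FPKM filter in both pairs. That kept all lower genes, but 206 of 282 genes higher with SALL4A and 339 of 390 higher with SALL4B. Genes under 1 FPKM with empty vector stayed only if both isoforms reached 1 FPKM, which favours sharing of higher genes. Independent lists would share 20 and 5.7, but unchanged libraries over a shared control shared 131 lower and 132 higher genes on average in simulations with resampled noise, at most 155 and 165. The simulated noise came from the ratios of SALL4A to SALL4B, so isoform differences raise these simulated counts. Across genes those ratios had a standard deviation of 0.74, against 0.669 for SALL4A and 0.701 for SALL4B over empty vector. The shared lower genes exceeded the simulated counts even so. For the shared higher genes, which lay under them, the simulation cannot decide whether sharing went beyond the control library. Opposite calls, which a shared control makes rare, were 7 genes higher with SALL4A and lower with SALL4B and 1 the reverse. Across 12217 genes the ratios had r = 0.543 and a covariance of 0.198, where 2 unchanged libraries against the same control gave 0.50 and 0.175 in simulation, a covariance difference of 0.024. Genes are not independent replicates, and with 1 control library part of the excess may come from that library.

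The third comparison set SALL4A against SALL4B directly. COL6A3 was at 115 FPKM with SALL4A and 7.07 with SALL4B (3.84), and the signalling regulators RGS4 (3.6) and UBASH3B (3.43) and the lipase LIPG (3.53) were also higher with SALL4A. ECSCR was at 10.1 FPKM with SALL4A and listed at 0 with SALL4B. ITLN1 was at 12.1 FPKM with SALL4B and listed at 0 with SALL4A, and CST7 (-3.56), APOA1 (-3.20), DCN (-3.16) and NTM (-2.87) were lower with SALL4A. The rule counted 474 of 12424 genes higher and 421 lower. Higher genes were 53% of these, and 64.4% with a common total, 69.5% with a common upper quartile and 73% with a common total without small RNAs.

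Nuclear OXPHOS genes were lower with SALL4A than with SALL4B, with a median of -0.38 (percentile 0.00) and 7 of 75 at least 2-fold lower. NDUFS4 (326 FPKM with SALL4B and 146 FPKM with SALL4A, -1.16), ATP5I (-1.32) and COX7C (-1.13) were among them, and UQCRB (-0.84) had the largest change in complex III. Complex I (-0.42) and complex III (-0.45) stood below, while complex II (-0.28), complex IV (-0.36) and complex V (-0.35) did not. Mitochondrial ribosomal proteins (-0.36), assembly factors (-0.23), with PET100 at -1.81, and cytosolic ribosomal proteins (-0.41) were also below. After correction for length and GC content the OXPHOS median was -0.21 (percentile 0.01).

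Lists of metabolism and cell state also separated the isoforms. Fatty acid oxidation (-0.36), NRF2 targets (-0.43, with NQO1 at 180 FPKM against 372), NF-kB targets (-0.47, CXCL1 at -2.20), hepatocyte markers (4 genes, -1.44) and biliary markers (-0.74) were lower with SALL4A. Without a filter on low values the biliary median was 0.027 and the hepatocyte median -0.159, and APOA1, a hepatocyte marker, passed the filter only through SALL4B. Higher with SALL4A were cholesterol synthesis (0.30), proliferation (0.16), histones (0.07), fibroblast markers (0.89), mesenchymal markers (0.19, with VIM at -2.33), endothelial markers (1.94) and leukocyte markers (0.89). The endothelial members were admitted mainly through the SALL4A library, and their median without a filter was 0.079, within its range. Of 14 alternatives, 3 ended the mesenchymal call. The 11 fibroblast markers were split, with 6 higher and 5 lower with SALL4A, from -3.165 to 3.148. Against empty vector the fibroblast median was lower with SALL4A (-1.117) than with SALL4B (-0.234), so these medians give no single direction. With genes at 5 FPKM or more, the fibroblast median between isoforms was -0.054.

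The fourth comparison asked what SALL4 knockdown changed in SNU-398 cells. The secreted stress factor GDF15 was at 18.0 FPKM after knockdown and 1.23 FPKM in untreated cells (3.09), and the transcription factor JUN was at 17.8 against 1.38 FPKM (2.98). S100A6 was listed at 0 in untreated cells and at 14.4 FPKM after knockdown, and the ferritin light chain FTL was at 2.205 and 30.3 FPKM (3.29). The lowest genes included the protease MMP10 (67.9 to 6.02 FPKM, -3.30), SLFN11 (-3.16), EMP1 (-3.14), the transcription factor BATF3 (-2.90), ANKRD1 (25.98 to 2.69 FPKM, -2.87), TPD52L1 (-2.83) and LRRCC1 (-2.80).

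RPL32, whose introns hold snoRNA genes, was at 138 FPKM in untreated and 1517 FPKM in knockdown cells (3.45). SCNN1D (3.19), LINC00351 (2.97), UBE2Q2L (2.80), GAS5-AS1 (2.79), an antisense partner of a snoRNA host, and LINC00478 (2.78) were also among the highest. CDR1 (-3.36), MYBPH (8.74 to 0.078 FPKM, -3.18) and SNAR-G1, at 11.4 FPKM in untreated cells and listed at 0 after knockdown, were among the lowest. The knockdown library was the shallowest and was compared with cells that the source label calls untreated. If that label holds, transduction and selection went with knockdown, but the protocol field lists both for every sample. In all, 1335 of 13716 genes lay at least 2-fold higher and 1115 lower.

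Higher genes were 54.5% of the knockdown counts, against 65.9% with a common upper quartile and 11.8% with a common total, which shifted the median gene by -0.60 because snoRNAs took 37.1% of the knockdown sum. Of 97 genes under 0.1 FPKM in untreated cells and at 20 FPKM or more on average in SNU-387, 89 lay above untreated in the knockdown library, at a median of 0.838% of their SNU-387 level. LDHB (5.08 FPKM), SPARC (5.23 FPKM) and KRT18 (3.53 FPKM) were among them, as was S100A6. Subtracting that share left 1301 genes on the higher side.

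Nuclear OXPHOS genes did not stand apart after knockdown, with a median of -0.08 (percentile 32.95), 1 gene at least 2-fold higher and 4 lower. ATP5G1 (37.8 to 12.3 FPKM, -1.55), ATP5D (-1.54) and NDUFA7 (-1.15) were lowest and COX6C highest (1.23). Complexes I to V had medians of -0.15, -0.14, -0.03, 0.12 and -0.07. Mitochondrial ribosomal proteins were lower (-0.36, percentile 0.06) with 8 of 77 at least 2-fold lower, led by MRPL11 (50.4 to 15.6 FPKM, -1.63). TCA cycle genes (-0.52, percentile 0.53) were lower, with SUCLG1 at -1.44 and IDH2 at -1.40, as were OXPHOS assembly factors (-0.33), with LYRM7 at -1.59, although 3 of 14 alternatives ended the latter call. Protein import (-0.25), fatty acid oxidation (-0.26, ETFB at -1.79) and mitochondrial DNA upkeep (0.09) were within range.

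Immediate early genes were higher after knockdown (0.88, percentile 100), with 7 of 18 at least 2-fold higher, among them FOS (7.58 to 42.0 FPKM, 2.32), while MYC was at -1.22. Interferon response genes had a median of 0.67 (13 genes, percentile 99.46), with DDX58 at 1.44 and IRF9 at 1.43. Of 14 alternatives, 1 (the mean over members) ended that call. The lowest median, 0.081, came with a common total, which shifts all genes, and kept the call. Unfolded protein and integrated stress response genes were at 0.42 (percentile 99.63), with DDIT3 going from 72.8 to 246 FPKM (1.74) and CRELD2 at -1.65. With a common total their median was -0.24, still at the percentile 99.53. NF-kB targets (0.64) and p53 targets (0.27, with 7 of 20 at least 2-fold higher, including BAX at 1.65) stayed within range.

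Proliferation genes were lower after knockdown (-0.42, percentile 0.38), with TYMS at -1.52 and MKI67 going from 235 to 122 FPKM (-0.94), and cytosolic ribosomal proteins were at -0.22 (percentile 0.03). Of the NuRD chromatin remodelling complex, a partner of SALL4, MBD3 was at -1.26 and GATAD2B at -1.15, with a list median of -0.43 (percentile 3.75, within range). Among oncofetal genes PEG10 (-1.98), HMGA2 (-1.30) and MYC were lower and LIN28B (1.07) and KLF4 (1.14) higher, with a list median of -0.16. Within range were glycolysis (0.19, although HK2 was at -2.74), hypoxia (0.19), NRF2 targets (-0.02, HMOX1 at 2.18), cholesterol synthesis (-0.07, STARD4 at 1.60), apoptosis regulators (0.13), histones (0.20), and genes used by every cell (0.05). Marker lists for mesenchymal (0.35), epithelial (0.78), fibroblast (0.04), hepatocyte (0.40) and biliary cells (-0.01) were within range too. Of 33 lists, 3 stood above and 6 below, the SALL family among the latter.

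**Figure D3:**
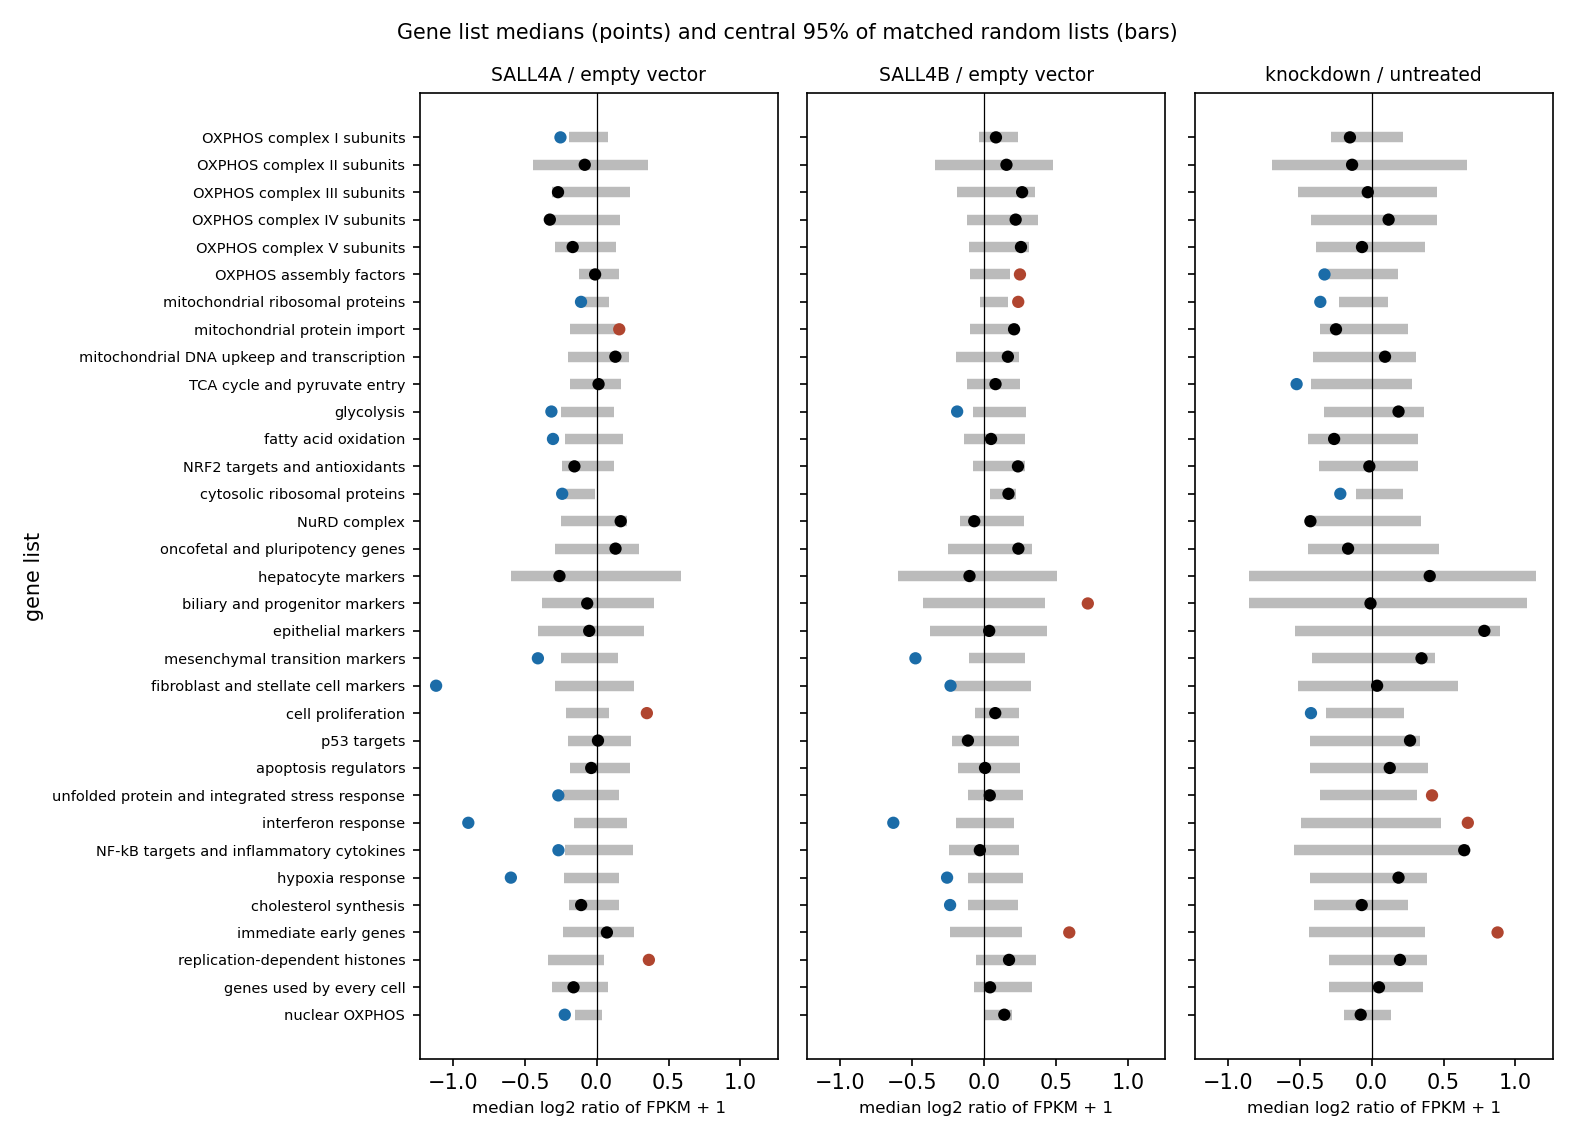
Median log2 ratio of FPKM + 1 (horizontal axis) for 33 gene lists (rows) in 3 pairs of libraries. Points are medians, coloured where they stand above or below the grey bars, which span the central 95% of matched random lists. Interferon response genes sit at -0.89, -0.63 and 0.67 from left to right.

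The last comparison looked for genes that moved one way with overexpression and the other with knockdown, pairs that share no control library. Higher with both isoforms and lower after knockdown were 6 genes, where independent lists gave 5.2. They were SALL4, ANKRD1, NCAM1 (4.73 to 0.879 FPKM after knockdown, -1.61), CCDC3 (-1.94), the triglyceride enzyme DGAT2 (-1.07) and the sialyltransferase ST6GAL1 (-1.13).

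Lower with both isoforms and higher after knockdown were 24 genes, where independent lists gave 7.4. Both numbers cover the 100 of 234 shared lower genes that also passed the 1 FPKM filter in SNU-398. Genes under 1 FPKM in untreated cells entered only if knockdown raised them, as with PLXDC2 (0.164 to 3.67 FPKM) and EREG (0.058 to 2.72 FPKM). The excess over 7.4 therefore cannot be separated from that filter. Subtracting the SNU-387 share took TGFBI, TTC34 and MTRNR2L8 of the 24 under 2-fold. The ephrin receptor EPHA3 was at 7.34 FPKM with empty vector, 0.031 FPKM with SALL4A and listed at 0 with SALL4B, and went from 10.8 to 45.1 FPKM after knockdown (1.96). PLXDC2 (-2.33, -2.13 and 2.005 for SALL4A, SALL4B and knockdown), the growth factor EREG (-2.16, -3.55 and 1.81) and GPNMB (-1.77, -1.87 and 2.54) shared the pattern. So did SLITRK6 (1.72 after knockdown), the integrin ITGB8 (1.44) and ITGBL1 (1.40). Under the same filter, genes higher with both isoforms and also higher after knockdown numbered 14 against 4.9. Genes lower in all 3 pairs numbered 7 against 7.8. Across 11087 genes, ratios after knockdown had r = 0.02 with SALL4A and -0.14 with SALL4B.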

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

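The tests in this part were all chosen after the results were seen. Mitochondrial ribosomal proteins had a median log2 ratio of -0.11 with SALL4A and 0.24 with SALL4B, opposite sides of their random ranges against the same empty vector library, and the difference was not tested across cultures. snoRNAs, which no comparison of named genes used, held 13.15% of summed FPKM with SALL4A and 8.1% with SALL4B against 7.14% with empty vector, and 37.14% after knockdown against 1.04% in untreated cells. Families that are silent in most tissues (olfactory, taste and vomeronasal receptors and keratin-associated proteins, 491 symbols) were above 0 for 55.4% of symbols in the knockdown library and 37.5% in untreated cells, and for 53.8% in the empty vector library against 9.2% with SALL4A and 7.9% with SALL4B.

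Genes abundant in SNU-387 lay above their untreated level in the knockdown library. Diffuse background alone is argued against, since the median excess was 10.46 times larger for genes at 50 FPKM or more in SNU-387 than for genes at 0.1 to 1 FPKM. A share of SNU-387 RNA or reads in that library, 0.838% at the median gene, may be a source, since 91.8% of the 97 genes lay above untreated. Choosing genes low in untreated cells favours such a count. Of 1026 genes equally low there but at 0.1 to 1 FPKM in SNU-387, 67.3% lay above untreated. In the other direction, 4 of 14 genes low in the knockdown library lay above it in untreated cells. SALL4 loss stays open. At least 2-fold lower with both isoforms were 13 of the 97, a larger share than the 234 of 12217 genes tested in both pairs. The 97 were chosen for high SNU-387 levels and the other genes were not matched to them, so this cannot decide between the sources. Subtracting the share removed 34 of 1335 higher genes, among them TGFBI (1.79 to 0.58) and NQO1 (1.33 to 0.96).

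Nuclear OXPHOS genes were lower with SALL4A. Their transcripts are short, with a median of 703 nt against 1742 nt for the tested genes. Correction for expression, length and GC content reduced the median from -0.22 to -0.11 and left the percentile at 0.61, which argues against these properties as the whole cause. An empty vector library standing apart is also argued against, because the list lay at the percentile 0.00 against SALL4B. SALL4A expression or an unlabelled difference of this library cannot be told apart with 1 SALL4A library, and either could account for what remains.

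Interferon response genes and collagens were lower with both isoforms. Background reads in the empty vector library are argued against, since 84.6% of 26 interferon list members exceeded the mean of both SALL4 libraries there by over 10 times the silent-family mean of 0.0946 FPKM. That SALL4 lowers interferon genes goes with their percentile of 99.46 after knockdown, a pair with no shared control. Only 13 of the 26 members passed the filter in that pair. Members under 1 FPKM in untreated cells entered only if knockdown raised them, although leaving out the filter did not end the call. The percentile was 99.34 after the SNU-387 share was subtracted, although 1 of 14 alternatives ended the call. Transduction could also raise these genes. By the source label it went with knockdown, while the protocol field lists it for every sample. The empty vector library standing apart cannot be told apart from an effect of both isoforms, because there was 1 empty vector library.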

How the results depend on the processing

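The length and GC correction, the common total without small RNAs, leaving out small RNAs and transcripts under 1 kb, and subtracting the SNU-387 share were chosen after seeing the data. SALL4 kept its direction and 2-fold size in all 24 values over the alternatives. Of 848 values of named genes, SALL4 included, 824 did so, and the remaining 24 fell under 2-fold in the same direction. Most named genes were picked for extreme ratios, which made that outcome likely. Depth limits genes near 1 FPKM most in the SALL4B and knockdown libraries. Adding tissue-restricted isoforms added no gene in SNU-387 and tested nothing there. Subtracting the SNU-387 share also tested nothing in the SNU-387 pairs, and centring could not end any list call. Where no cause is named, the cause was not tested.

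A pseudocount of 0.1 FPKM gave 516 higher and 648 lower genes for SALL4A, 681 higher for SALL4B, and 739 higher and 711 lower for SALL4A against SALL4B. It gave 550 genes shared by both isoforms, and 18 and 52 genes opposite to knockdown. A pseudocount of 5 FPKM gave 113 and 161 for SALL4A, 139 and 265 for SALL4B, 194 and 154 between isoforms, 508 and 382 for knockdown, 136 shared, and 2 and 4 opposite. The 1.5-fold rule by construction gave more: 1085 and 1212, 1348 and 1323, 1331 and 1533, 2914 and 2858 in the same order, 920 shared, and 83 and 106 opposite.

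A common total gave 531 higher and 3982 lower genes after knockdown, 19 and 12 opposite, an OXPHOS median of -0.73 and a stress response median of -0.24, following the snoRNA share of the sum. A common upper quartile gave 191 and 975 for SALL4B, 255 lower between isoforms, 46 lower with SALL4 and higher after knockdown, and SALL4B medians of -0.20 for OXPHOS, -0.074 for assembly factors and -0.095 for mitochondrial ribosomal proteins. It gave -0.037 for protein import with SALL4A. It shifted the median gene by -0.18, -0.31, 0.13 and 0.11 in the order of the pairs.

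Without a filter, biliary medians were -0.028 for SALL4B and 0.027 between isoforms. At 5 FPKM or more, the fibroblast median between isoforms was -0.054, and 3 genes were higher with SALL4 and lower after knockdown. Without complex I, OXPHOS medians were -0.17 for SALL4A (percentile 5.29) and 0.22 for SALL4B. A common total without small RNAs gave 235 lower genes between isoforms. Without small RNAs and transcripts under 1 kb, with fewer genes tested, 164 genes were higher for SALL4A, 304 higher and 253 lower between isoforms, and 887 higher after knockdown.

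For lists that stood apart, 1 alternative ended the call for nuclear OXPHOS, endothelial, proliferation and NF-kB lists with SALL4A, and for glycolysis, leukocyte and cholesterol lists with SALL4B. It was 1 also for complex III, fatty acid oxidation, NRF2, endothelial, leukocyte, cholesterol, biliary and histone lists between isoforms, and for stress response and interferon lists after knockdown. Between isoforms 2 ended the proliferation call and 3 each the fibroblast and mesenchymal calls. With SALL4A 2 ended the import, cytosolic ribosomal and stress response calls and 4 the mitochondrial ribosomal call. With SALL4B 2 ended the biliary call and 4 the fibroblast call, and after knockdown 3 ended the assembly factor call.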

Other observations

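The gene families and tests in this part were all chosen after the data were seen. Collagens, the main fibrous proteins of the matrix, had a median log2 ratio of -0.93 with SALL4A (13 of 32 at least 2-fold lower, 1 higher) and -1.11 with SALL4B (20 of 31 lower, 3 higher), both at the percentile 0.00. COL1A1 went from 54.9 FPKM to 18.6 and 4.92 FPKM and COL3A1 from 141 FPKM to 17.2 and 8.80 FPKM. COL4A1 was at 73.5 FPKM with empty vector, 108 FPKM with SALL4A and 10.8 FPKM with SALL4B. After knockdown the collagen median was 0.73 (percentile 99.41), with COL12A1 at 14.6 against 1.74 FPKM, and 0.61 (percentile 97.64) once the SNU-387 share was subtracted.

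Integrin subunits had medians of -0.54 and -0.64, serpins of -0.68 and -0.56, and HLA genes of -0.65 and -0.63 with SALL4A and SALL4B, each below its random range. After knockdown none of these families stood apart. Integrin subunits were at 0.40 (percentile 85.01), serpins at -0.275 (percentile 8.23) and HLA genes at 0.09 (percentile 37.83). Metallothioneins, which bind metals, were higher with SALL4B (0.52, percentile 99.44) and not with SALL4A (-0.04), and that difference was not tested across cultures. Zinc finger genes named ZNF had a median of 0.34 after knockdown (405 genes, percentile 100), with 59 at least 2-fold higher and 17 lower, and 0.28 after correction for length and GC content. With SALL4A their median was also positive (0.09, percentile 98.86), but 0.03 (percentile 83.41) after that correction. With SALL4B it was -0.05 (percentile 4.57), within range.

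ANKRD1 is a target of YAP and TEAD, and it was higher with both isoforms and lower after knockdown. The hypothesis that other targets moved with it was tested on 22 target genes without ANKRD1. Their medians were 0.43 with SALL4A (percentile 100) and 0.32 with SALL4B (percentile 99.45), as the hypothesis predicted, although only 3 and 4 of 21 were at least 2-fold higher and CTGF was 2-fold lower with SALL4B (-1.08, and 0.07 with SALL4A). After knockdown the median was 0.02 (percentile 62.59), which goes against it for SNU-398 cells. Raised YAP activity in SNU-387 cells with SALL4 may be worth testing, and a difference of the empty vector library stays open.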
